A study of Homo sapiens and Mus musculus with 12 samples.

How the data were processed

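RNA-seq libraries were made from cortical organoids, 3-dimensional aggregates of stem cells that differentiate toward embryonic forebrain tissue. The human organoids came from H9 embryonic stem cells, an established line, and their genotype was labelled either WT or NOTCH2NL knockout (KO). They were harvested at week 4, on day 28, and each replicate was a pool of 5 to 10 organoids. The mouse organoids came from 46C embryonic stem cells, an established mouse line, that carried either an empty vector (EV) or a vector expressing the NOTCH2NL-Sh_T197I form of the human gene (N2NL). They were harvested after 6 days, and each replicate was a pool of 16 organoids. Each of the 4 groups had 3 libraries. Per the labels' protocols, polyadenylated RNA was selected and libraries were made with a strand-specific kit for Ion sequencers. The sample descriptions carry 1 line code for WT (H9_WT_E2del19) and 1 for KO (H9_KO_E5del42), whose meaning is not given in the sources used here, so the human genotype and the line it was measured in are the same division of the libraries. In mouse, all EV libraries carry the line code 46C_EV and all N2NL libraries 46C_N2NL, so vector and line are the same division too. The labels do not say that the pools of a group came from separate cultures. The p-values therefore measure the spread between pools, which may in part be technical.

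The authors deposited, for each species, a table of raw read counts per Ensembl gene and a table of their own DESeq2 comparison. The submitters' processing notes name Trimmomatic 0.36, STAR 2.4.0, Bowtie2 2.3.3.1, HTSeq 0.6.1p1 and DESeq2 2.11.39 and the builds GRCh38 (hg38) for human and GRCm38 (mm10) for mouse, without giving the role of each tool; the strand setting of the counting is not given in the sources used here. The deposited counts are whole numbers and were used as they stand. The authors' comparison tables hold, per the file headers, normalized values per library, which were treated as a score, a mean, a log2 fold change with its standard error, a test statistic, a p-value and an adjusted p-value. From these tables only the authors' calls, the NOTCH2NL row of the mouse table and single values named as theirs are printed. In the human table the authors' normalized columns of replicates 1 and 3 follow the raw count columns of replicates 3 and 1 in both groups (SD of the log2 ratio at most 0.0018 over 10953 genes, against at least 0.2389 for the columns of the same name). Replicate numbers in the text are those of the raw count columns, and the exchange stays within a group. All columns of values per sample were assigned to a sample.

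Total counts per library ran from 15381409 to 16382938 in human over 60675 gene identifiers and from 16781742 to 20960391 in mouse over 47729. A count of 0 in 1 library allows a level of up to 0.195 CPM in human and 0.179 in mouse, from a floor of 3 counts, which covers counting error only. The mouse table also holds the counter's summary lines, which name no gene and were left out of library sizes and tests. They amounted to 5.77% to 6.5% of reads outside genes, 0.77% to 0.91% ambiguous, 4.42% to 5.65% of low alignment quality and 26.64% to 33.67% aligned to several places. Genes that share reads with near-identical copies, among them NOTCH2NL and NOTCH2, ribosomal protein genes, histone genes and members of large zinc finger families, are therefore uncertain. So are genes that overlap another gene on the opposite strand, such as DLX6 and DLX6-AS1.

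Human gene symbols came from the authors' deposited table. Of the human identifiers, 57055 were found in GENCODE release 29, which gave GRCh38 coordinates and gene types. No mouse annotation was used here. Mouse genes were matched by hand to the members of the gene lists from the gene descriptions in the authors' deposited table, which gave 508 genes. With the genes past the authors' threshold, 606 were matched, among them 129 of the 147 such genes that have raw counts. The planned matching of all genes by symbol was replaced by this matching, so every comparison between species covers list genes only, and no shift of mouse chromosomes was computed.

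Each species was tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr, libraries were scaled by TMM factors, and KO was compared with WT, and N2NL with EV, by the robust quasi-likelihood F test with no term other than the group. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called higher or lower. Levels are CPM with TMM factors, given as mean ± SD of 3 libraries, and folds are on the log2 scale. The ± of a fold is an approximate standard error, the size of the fold divided by the square root of the F statistic. For a gene at 0 in all libraries of a group, the fold is a lower bound computed from a floor of 3 counts over the group. An exact permutation test of 3 against 3 libraries cannot give a two-sided p under 0.1, so single genes were not tested that way.

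There were 31 gene lists for human and 29 for mouse: Notch target genes; Notch ligands, receptors and modifiers; radial glia; proneural and intermediate progenitors; neurons; deep-layer and Cajal-Retzius neurons; dorsal telencephalon; ventral telencephalon; cortical hem and choroid plexus; midbrain, hindbrain and spinal cord; retina and pigment epithelium; neural crest and mesenchyme; surface epithelium; mesoderm and endoderm; endothelium, blood and microglia; pluripotency; mitotic cell cycle; astroglia and oligodendrocytes; hypoxia and glycolysis; amino acid and unfolded protein stress; p53 targets; immediate early genes; cholesterol synthesis; extracellular matrix; WNT targets; SHH targets; mitochondrially encoded genes; ribosomal protein genes; replication-dependent histone genes; and, in human only, the distal and proximal 1q21.1 intervals. Each list with at least 5 tested genes was tested against the other genes with camera (limma 3.58.1, preset correlation 0.01, two-sided, Benjamini-Hochberg over the lists of a species). Human chromosomes with at least 20 tested genes were tested the same way. Members called over all genes are given beside those called when adjusted over the list alone.

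The design, these tests, the lists, the rule for naming genes and the alternatives listed first in the next paragraph were fixed before the data were examined. The rule names the NOTCH2NL genes and NOTCH2. It also names the 10 largest rises and falls among called genes whose mean is at least 5 CPM in the higher group and whose groups do not overlap, leaving out pseudogenes and clone names. Of each called list or list with at least 3 called members it names the 4 members with the smallest adjusted p, and of other lists up to 2. Some genes that the rule names are not reported here. Its filter for pseudogene names (a final P and digit) also removes ZFP28 and SP9. Of the mouse genes, some ribosomal protein and histone members are known by description only.

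The alternatives fixed in advance were DESeq2 1.42.0, limma-voom, RLE factors, library size alone, no filter or a stricter filter (CPM of 1 in 3 libraries), no robust step, thinning to the smallest library, the replicate number as a block, each library left out, camera with an estimated correlation, and fry. Added after seeing the data were DESeq2 with the block, each replicate number left out of both groups, and the authors' mouse calls as gene sets in human. Fold changes of the 2 species were compared by Spearman and Pearson correlation across matched genes. Genes are not independent, so the value was set beside those of all 100 pairs of splits of the libraries. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

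The test was run on simulated data drawn from the real means and library sizes, with 200 genes changed. With dispersions from the trend, folds of 1.5, 2 and 4 were recovered for 47.8%, 80.6% and 100% of the changed genes in human (16698 genes tested, 5.6% of 161 calls false) and for 79.1%, 89.6% and 100% in mouse (16475 genes tested, 5.3% of 189 calls false). With dispersions of single genes, 46.3%, 67.2% and 89.4% were recovered in human (16685 genes, 15.1% of 159 calls false) and 74.6%, 85.1% and 98.5% in mouse (16446 genes, 9.5% of 190 calls false). A list with planted changes was called in each simulation and no other list was. Each gene was drawn independently, so these simulations cannot show how often camera calls a list whose genes vary together. A simulated 1.5-fold shift of chromosome 21 was called, with a median of 0.57 on the log2 scale, and no other chromosome was.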

Results

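The data are gene-level read counts from 12 RNA-seq libraries of cortical organoids. NOTCH2NL genes are human-specific partial copies of NOTCH2, the receptor gene of the Notch pathway from which they derive. The human part asks how week 4 organoids change when NOTCH2NL is lost, with 3 WT and 3 KO libraries. The mouse part asks how day 6 organoids change when 1 NOTCH2NL form is expressed in a species that lacks the gene, with 3 EV and 3 N2NL libraries. Human libraries held 15514521, 16382938 and 15558342 counts (WT 1 to 3) and 15404138, 15381409 and 16306480 counts (KO 1 to 3). Mouse libraries held 18436984, 20960391 and 20488836 counts (EV 1 to 3) and 20381366, 16896849 and 16781742 counts (N2NL 1 to 3).

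In human, the first principal component of the log2 CPM held 48.8% of the variance and parted all 3 WT libraries (-38.29 to -30.74) from all 3 KO libraries (31.17 to 35.12). WT 1 lay at 35 on the second component (22.1%), above the other WT libraries at -27.97 and -11.24. KO 3 lay at -23.04 on it, below the other KO libraries at 11.46 and 15.78. In mouse, the first component held 29.3% and did not part the groups: the replicate 1 libraries of EV and N2NL lay at -21.98 and -19.08, and the other 4 between 1.04 and 20.53.

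**Figure D1:**
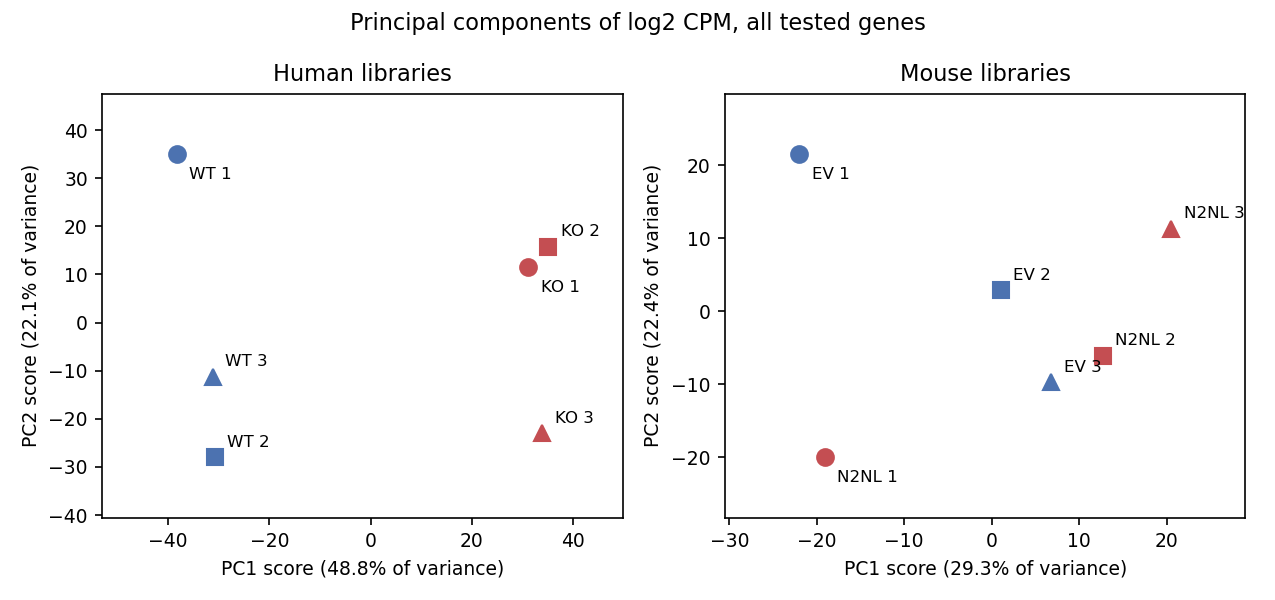
Position of each library on the first (x axis) and second (y axis) principal component of log2 CPM, with the share of variance on each axis label, for human (left) and mouse (right); each point is 1 library. WT and KO lie apart on the human x axis, while the mouse x axis sets the replicate 1 libraries of both groups, at -21.98 and -19.08, apart from the rest.

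The targeted gene was read first. NOTCH2NL (ENSG00000264343, named NOTCH2NLA in GENCODE 29; GRCh38 chromosome 1, 146146203 to 146229026, minus strand) had 4, 5 and 3 counts in WT 1 to 3 and 0 counts in all 3 KO libraries. These counts go with the labels but did not pass the filter on low counts, so the gene was not tested, and reads shared with near-identical copies make the gene's level uncertain. NOTCH2 (ENSG00000134250; chromosome 1, 119911553 to 120069626, minus strand) stood at 135 ± 13.8 CPM in WT and 151 ± 25.7 CPM in KO (SD, n = 3 each), a log2 fold change of 0.16 ± 0.13 that did not pass the test (edgeR quasi-likelihood, adjusted p = 0.491).

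As lists, ventral telencephalon genes were higher and hypoxia and glycolysis genes lower in KO than in WT by camera (adjusted p = 6.00e-11 and 4.36e-04), calls that were lost at an adjusted p = 0.680 for both with an estimated correlation. The DLX homeobox genes, which specify ventral forebrain and its inhibitory neurons, rose: DLX2 (ENSG00000115844; chromosome 2, 172099439 to 172102900) went from 1.34 ± 0.485 to 51.4 ± 15.8 CPM, and DLX5 from 1.78 ± 1.05 to 49.4 ± 14.5 CPM (SD, n = 3). SIX3, a homeobox gene of the anterior forebrain and eye field, rose from 7.66 ± 1.43 to 31.2 ± 6.12 CPM. Aldolase C (ALDOC), a glycolytic enzyme gene, fell from 35.1 ± 5.74 to 9.65 ± 1.08 CPM. PUS7L, a pseudouridine synthase-like gene, had 229, 179 and 200 counts in WT 1 to 3 and 0 in every KO library, at least 206-fold lower.

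In all, 391 genes were higher and 541 lower in KO among 16956 tested (edgeR quasi-likelihood, Benjamini-Hochberg). With library size alone in place of TMM factors, 454 were higher and 455 lower, so the excess of lower genes depends on the scaling. The 3 libraries of one group lay wholly above those of the other for all 932 called genes and for 28.8% of the tested genes, where chance gives 10%. The count ran from 224 to 1440 when 1 library was left out: 1440 without WT 1, 499 without WT 2, 224 without WT 3, 251 without KO 1, 506 without KO 2 and 526 without KO 3. The authors' deposited table holds 1348 genes past an adjusted p of 0.05, and 914 of the 932 are among them with the same direction.

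Among the 10 named largest rises, 5 were DLX2, DLX5, DLX1, DLX6 and the DLX6 antisense transcript DLX6-AS1. Their log2 fold changes were 5.27 ± 0.32, 4.81 ± 0.45, 4.70 ± 0.53, 3.76 ± 0.69 and 4.66 ± 0.63. DLX1 and DLX2 lie close together on chromosome 2, and DLX5, DLX6 and DLX6-AS1 on chromosome 7, so these rises may not be independent. DLX2, DLX5 and DLX1 had adjusted p-values of 2.41e-04, 0.00499 and 0.0135 in edgeR. Each was higher in 3 of 3 KO libraries than in any WT library, which the rule for naming the largest rises requires. DLX1 was not called without WT 1 or without KO 1. DLX6 (adjusted p = 0.0480) was called in 1 of the 6 edgeR fits that left out a library, that without WT 2, and DLX6-AS1 (0.0250) in 3. VAX1 (3.46 ± 0.70), a ventral forebrain and optic stalk homeobox gene, and ISL1 (3.25 ± 0.34), a LIM homeobox gene of ventral forebrain and motor neurons, rose too. VAX1 (edgeR adjusted p = 0.0371) was called in 1 of the 6 fits that left out a library, that without WT 1, and ISL1 (7.56e-04) in all 6. PKIB, an inhibitor of protein kinase A, rose from 1.63 ± 0.332 to 24.5 ± 1.84 CPM (3.90 ± 0.19, edgeR adjusted p = 7.74e-06). The remaining named rises were CLRN1-AS1 (5.24 ± 0.48), a noncoding transcript, and SLITRK6 (3.17 ± 0.31), a neuronal membrane protein gene.

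Of the 10 named largest falls, 5 had 0 counts in all KO libraries: PUS7L (ENSG00000129317; chromosome 12, 43718993 to 43758817), its neighbour IRAK4 (ENSG00000198001; chromosome 12, 43758944 to 43789543), a kinase of Toll-like receptor signalling, TRIM4, and the zinc finger genes ZNF135 and ZNF595. IRAK4 was at least 83.6-fold lower (5.28 ± 0.333 CPM in WT), TRIM4 at least 147-fold (9.27 ± 0.172), ZNF135 at least 180-fold (11.4 ± 0.780) and ZNF595 at least 97.2-fold (6.14 ± 1.03). PHACTR3, a phosphatase and actin regulator, fell from 30.8 ± 1.58 to 0.106 ± 0.0737 CPM (-8.09 ± 0.27, edgeR adjusted p = 3.21e-07). ZNF354C (-6.97 ± 0.47), BEX5 (-6.62 ± 0.40), the lactate transporter gene SLC16A3 (-4.81 ± 0.49) and ZNF311 (-4.21 ± 0.42) completed the falls. All 10 kept their calls in all 6 fits that left out a library.

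**Figure D2:**
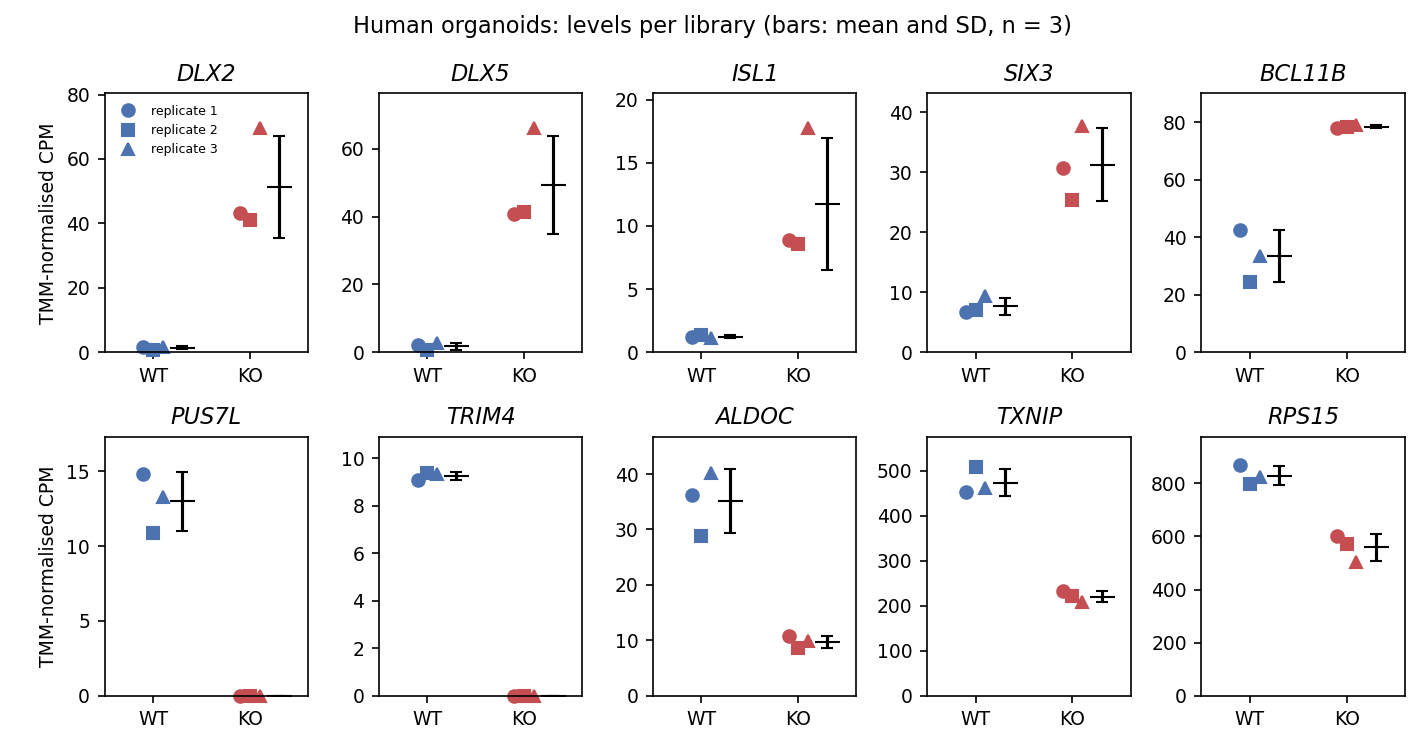
CPM with TMM factors (y axis, starting at 0) of human genes named in the text in each WT and KO library; points are libraries, and bars give the mean and SD of 3. DLX2 stands at 1.34 ± 0.485 CPM in WT and 51.4 ± 15.8 CPM in KO, and PUS7L has 179 to 229 counts in WT and 0 in all 3 KO libraries.

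Among the 31 gene lists, 6 were called in KO against WT by camera with the preset correlation, 3 higher and 3 lower. None was called with an estimated correlation in human or in mouse, and for each of these 6 lists the estimated correlation gave the highest adjusted p of all alternatives run. Of 11 tested ventral telencephalon genes, 5 rose, none fell and 6 did not pass, and 6 were higher and 1 lower adjusted over the list alone. The list had a median log2 fold change of 1.07 ( camera adjusted p = 6.00e-11, or adjusted p = 0.680 with an estimated correlation). The 5 were ISL1, the neighbours DLX1 and DLX2, and the neighbours DLX5 and DLX6. Cortical hem and choroid plexus genes had 3 of 22 rise (4 adjusted over the list alone), the signalling genes BMP7 (28.0 ± 6.69 to 61.8 ± 15.6 CPM) and BMP6 (1.76 ± 0.579 to 4.30 ± 0.825 CPM) and the homeobox gene MSX1 (15.8 ± 5.40 to 35.4 ± 5.58 CPM). That list had a median of 0.59 (camera adjusted p = 6.34e-04, or adjusted p = 0.680 with an estimated correlation). Mitotic cell cycle genes had 2 of 27 rise (7 adjusted over the list alone), cyclin B1 (CCNB1, 0.50 ± 0.11) and the kinetochore motor gene CENPE (0.73 ± 0.16), with a median of 0.23 (camera adjusted p = 5.89e-04, or adjusted p = 0.795 with an estimated correlation). The proliferation marker MKI67 stood at 0.61 ± 0.16 and did not pass (edgeR adjusted p = 0.0607). BMP7, CCNB1 and CENPE were each called in 2 of the 6 fits that left out a library, and BMP6 and MSX1 in 1. The mitotic call ended without WT 2 (camera adjusted p = 0.121; 6.55e-10 to 0.795 over the alternatives).

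Ribosomal protein genes had 20 of 78 fall and none rise (47 adjusted over the list alone), and 76 of the 78 log2 fold changes lay below 0 (median -0.27, camera adjusted p = 7.25e-15, or adjusted p = 0.680 with an estimated correlation). RPS15 fell from 830 ± 36.3 to 559 ± 50.0 CPM (edgeR adjusted p = 0.00761); RPL18 and RPS27 fell by 0.50 ± 0.09 and 0.52 ± 0.10 on the log2 scale. Hypoxia and glycolysis genes had 5 of 23 fall (9 lower and 1 higher adjusted over the list alone; median -0.23, camera adjusted p = 4.36e-04, or adjusted p = 0.680 with an estimated correlation). Among them were ALDOC (-1.86 ± 0.16, edgeR adjusted p = 2.41e-04), the neuronal enolase gene ENO2 (-0.69 ± 0.08, 0.00127), the pyruvate dehydrogenase kinase gene PDK1 (30.8 ± 3.85 to 15.9 ± 1.42 CPM, 0.00438) and lactate dehydrogenase A (LDHA, 183 ± 17.9 to 103 ± 27.1 CPM, 0.0370). Midbrain, hindbrain and spinal cord genes had 1 of 17 fall, PAX8 (39.3 ± 10.7 to 9.75 ± 3.59 CPM), 15 of 17 fold changes below 0 and a median of -0.84 (camera adjusted p = 0.00487, or adjusted p = 0.795 with an estimated correlation). GBX2 and PAX7 stood at -1.56 ± 0.55 and -1.04 ± 0.45 and did not pass. When 1 library was left out, PAX8 and RPL18 were each called in 4 of the 6 fits, RPS27 in 2 and LDHA in 1. The midbrain call ended without KO 2 (camera adjusted p = 0.0506; 2.77e-09 to 0.795 over the alternatives). The number of lists called was 12 without WT 1 and 10 without WT 3.

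The 12 Notch targets were not called as a list (median -0.08, camera adjusted p = 0.265). Neither were the 26 Notch ligands, receptors and modifiers (median -0.05, camera adjusted p = 0.0858), a list that was called lower without WT 1 or KO 3 (lowest camera adjusted p = 0.0243). Of the targets, HES4, a transcriptional repressor induced by Notch, fell from 65.4 ± 4.77 to 39.6 ± 6.80 CPM and the receptor gene NOTCH3 from 163 ± 4.10 to 128 ± 6.07 CPM, and 10 did not pass (2 lower adjusted over the list alone). Of the others, DLK1, a noncanonical ligand gene, fell from 105 ± 8.97 to 61.6 ± 9.02 CPM, the ligand gene JAG2 from 13.6 ± 2.01 to 8.42 ± 0.982 CPM, and NOTCH1 fell by 0.39 ± 0.10 on the log2 scale. The other 23 did not pass, and 5 were lower adjusted over the list alone. The 5 called Notch genes had edgeR adjusted p-values of 0.0131 (HES4), 0.0321 (NOTCH3), 0.00597 (DLK1), 0.0423 (JAG2) and 0.0456 (NOTCH1). HES4 and DLK1 were called in 5 of the 6 fits that left out a library, all but that without WT 3. NOTCH3 and JAG2 were called in 1 of these fits, that without WT 1, and NOTCH1 in 1, that without WT 2. NUMBL, an intracellular Notch antagonist, stood at -0.36 ± 0.10 (edgeR adjusted p = 0.0570).

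Cell type lists that were not called held single changed genes. Of 32 neuron genes, the membrane glycoprotein gene GPM6A (354 ± 4.47 to 267 ± 10.9 CPM), the tubulin gene TUBB3 (26.4 ± 1.45 to 18.3 ± 1.48 CPM) and the microtubule gene MAPT (404 ± 35.6 to 313 ± 13.1 CPM) fell. The other 29 did not pass, and 4 were lower and 1 higher adjusted over the list alone (median -0.18, camera adjusted p = 0.0928). Of 16 deep-layer and Cajal-Retzius genes, the transcription factor genes BCL11B (33.5 ± 8.97 to 78.5 ± 0.616 CPM) and FOXP2 (10.6 ± 3.98 to 29.2 ± 6.16 CPM) rose, with 2 higher and 1 lower adjusted over the list alone. Membership in the list does not make either gene particular to these neurons. The median (-0.09) and mean (-0.03) of that list lay below 0 and its test pointed up (camera adjusted p = 0.676). Of 17 dorsal telencephalon genes only SIX3 passed (2 higher adjusted over the list alone; median 0.15, camera adjusted p = 0.0575), and SP8 stood at 1.23 ± 0.28 (edgeR adjusted p = 0.0535). Of 21 radial glia genes the membrane gene TTYH1 fell from 675 ± 32.7 to 484 ± 17.1 CPM (3 higher and 1 lower adjusted over the list alone; 0.449). Of 17 proneural genes GADD45G rose (11.3 ± 2.70 to 20.5 ± 0.992 CPM) and BTG2 fell (39.3 ± 3.70 to 27.3 ± 3.30 CPM), the same 2 adjusted over the list alone (0.913; median and mean 0.02, test down). Of 10 retina and pigment epithelium genes 2 rose and 1 fell, among them TYRP1 (0.124 ± 0.160 to 1.77 ± 0.124 CPM) and PMEL (3.93 ± 1.30 to 1.13 ± 0.545 CPM), with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0907). As lists, dorsal telencephalon genes were called higher without WT 1, WT 3 or KO 3 (lowest camera adjusted p = 9.68e-04) and retina genes without WT 2, WT 3 or KO 1 (0.00739). Neuron genes were called lower without WT 1 or KO 3 (0.00234) and radial glia genes higher without WT 1 (0.0476). Over the 6 fits that left out a library, BCL11B, TTYH1 and TYRP1 were each called in 5, GADD45G in 3, GPM6A, FOXP2 and PMEL in 2 and TUBB3, MAPT and BTG2 in 1.

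Of 12 neural crest and mesenchyme genes LUM fell (-2.04 ± 0.40) and PDGFRB rose (1.13 ± 0.25), also adjusted over the list alone (camera adjusted p = 0.449). Of 11 astroglia and oligodendrocyte genes SOX8 fell (-0.60 ± 0.15; 1 higher and 2 lower adjusted over the list alone; 0.734). No member passed among 6 surface epithelium (0.913), 8 mesoderm and endoderm (0.913, median -0.05, mean 0.04), 5 endothelium, blood and microglia (0.325) and 8 pluripotency genes (0.676), over all genes by edgeR or adjusted over the list alone. Of 18 p53 targets RRM2B (-0.63 ± 0.14) and BBC3 (-0.70 ± 0.17) fell (5 lower adjusted over the list alone; camera adjusted p = 0.0871). Of 13 immediate early genes EGR3 rose (2.47 ± 0.34) and IER2 fell (-0.52 ± 0.09), with 1 higher and 3 lower adjusted over the list alone (0.913). Of 22 histone genes HIST1H2AC (1.63 ± 0.30) and HIST1H3E (2.47 ± 0.53) rose, the same number adjusted over the list alone (0.0575). No member passed among 13 WNT targets (0.913, 1 lower adjusted over the list alone), 6 SHH targets (0.265), 20 stress (0.913, median -0.01, test up), 19 cholesterol (0.871, median 0.05, mean -0.01), 22 extracellular matrix (0.617) and 13 mitochondrially encoded genes (0.158). The histone list was called higher without WT 2, WT 3, KO 1 or KO 2 (lowest camera adjusted p = 0.00610). The neural crest list was called lower without WT 1 (0.0482), the p53 list lower without WT 2 (0.0198) and the mitochondrially encoded list higher without WT 3 (0.00720). Without 1 library, IER2 and HIST1H2AC were each called in 4 of 6 fits, LUM and HIST1H3E in 3, RRM2B in 2 and PDGFRB, SOX8 and BBC3 in 0. In the proximal 1q21.1 interval beside NOTCH2NL, TXNIP (ENSG00000265972; chromosome 1, 145992435 to 145996600), a thioredoxin-binding regulator of glucose uptake, fell from 474 ± 29.9 to 220 ± 11.9 CPM (-1.11 ± 0.09, edgeR adjusted p = 1.73e-04). ITGA10 rose (1.78 ± 0.46, 0.0496; called in 2 of the 6 fits that left out a library) and 12 genes of the interval did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0642, fry adjusted p = 0.0192, and camera adjusted p = 0.0482 without WT 1). None of 7 distal interval genes passed (camera adjusted p = 0.913).

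**Figure D3:**
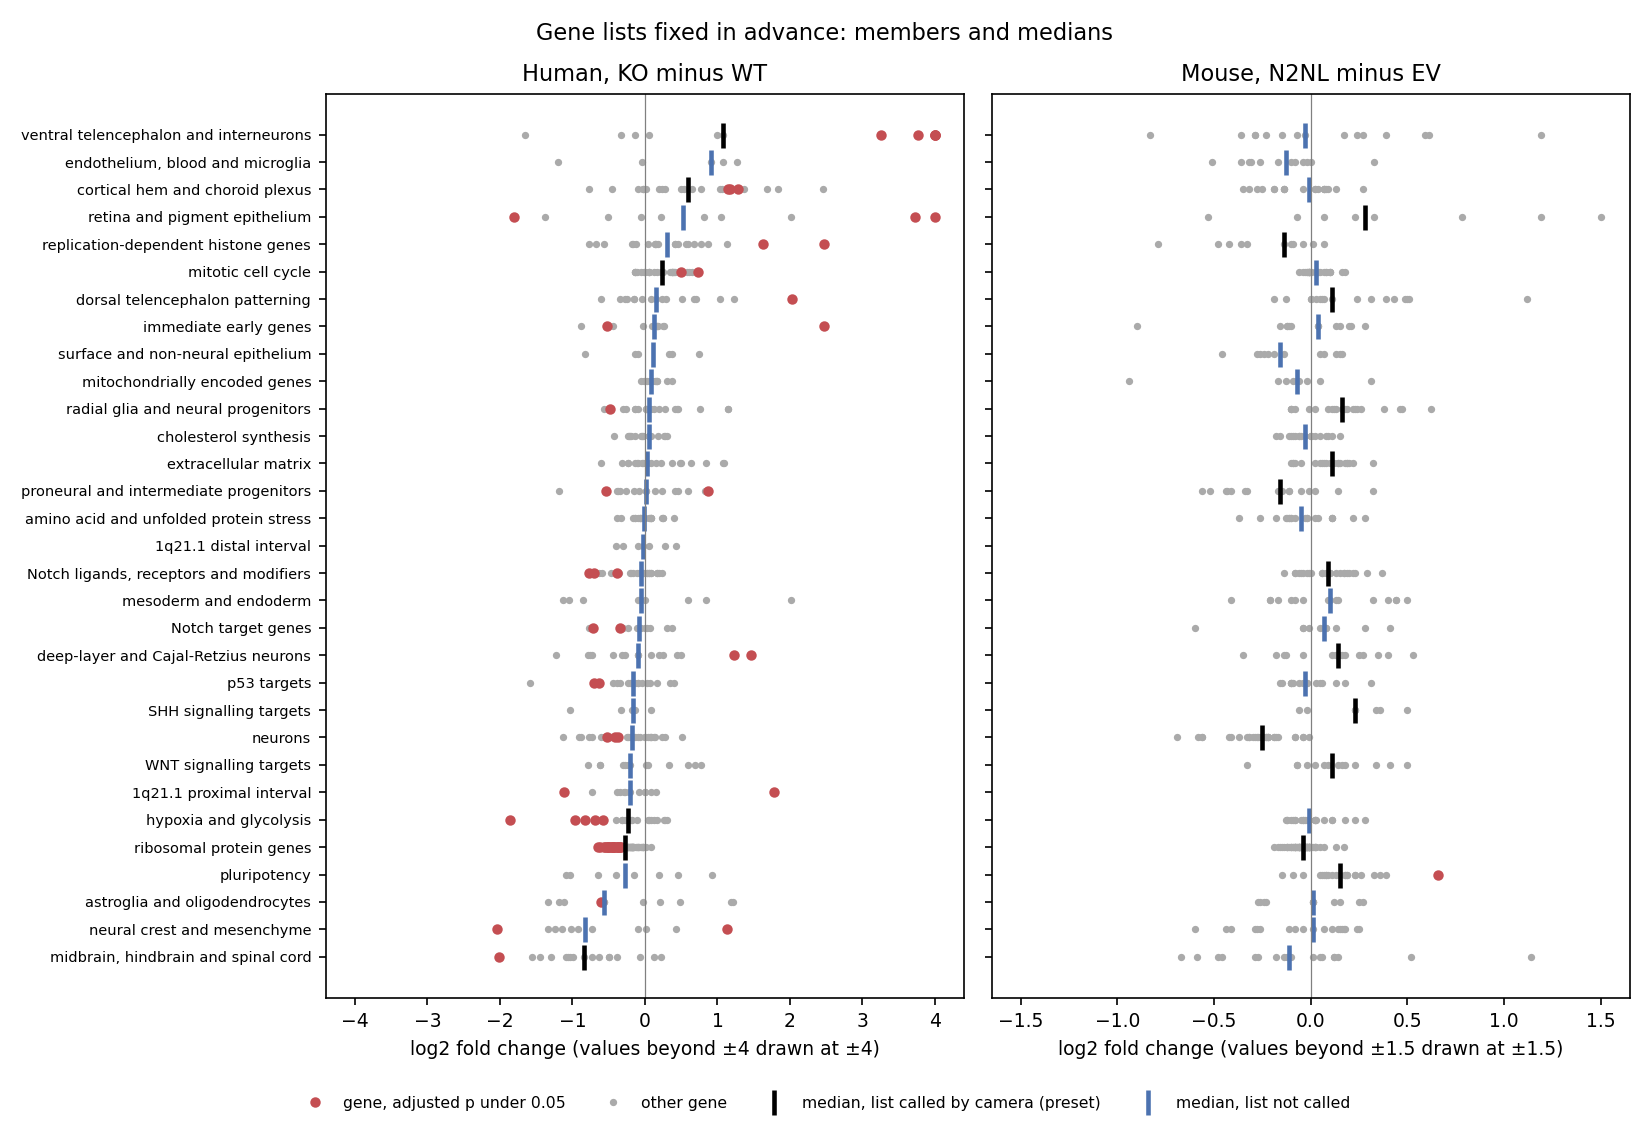
Log2 fold change (x axis) of each tested member (points) and the median (bar) of the gene lists (y axis) in human KO against WT (left) and mouse N2NL against EV (right); values beyond the axis limits are drawn at the limit, and the 1q21.1 lists are human only. The human ventral telencephalon median lies at 1.07, and all 31 mouse neuron genes lie below 0.

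Of 24 chromosome groups only the mitochondrial genome was called (26 genes, median 0.15, camera adjusted p = 0.00355), and the other medians lay between -0.05 and 0.06 (lowest adjusted p = 0.699). Each median lay below the 0.57 that a simulated 1.5-fold shift of chromosome 21 gave. Chromosomes were tested with the preset correlation only. The list of 13 mitochondrially encoded genes was not called (camera adjusted p = 0.158, or adjusted p = 0.840 with an estimated correlation).

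In mouse organoids with NOTCH2NL, the neuron and proneural lists were lower and the dorsal telencephalon and radial glia lists higher than with the empty vector by camera with the preset correlation. None of these 4 calls held with an estimated correlation (adjusted p = 0.186 for dorsal telencephalon and adjusted p = 0.401 for the other 3), and 2 single genes passed the edgeR test. Each mouse group has 1 line code, so an effect of the vector and a trait of the line cannot be told apart. Neuronatin (Nnat, ENSMUSG00000067786), an imprinted gene of developing brain, rose from 302, 539 and 436 counts in EV 1 to 3 to 993, 993 and 932 counts in N2NL 1 to 3, a 2.58-fold rise in CPM (1.37 ± 0.14 on the log2 scale, edgeR quasi-likelihood adjusted p = 0.0143). Klf2 (ENSMUSG00000055148), a Kruppel-like factor of naive pluripotency, rose from 25.3, 23.6 and 26.0 to 38.0, 42.4 and 37.7 CPM (0.66 ± 0.09, edgeR adjusted p = 0.0368). All 3 N2NL libraries lay above all 3 EV libraries for both genes, which the rule for naming the largest rises requires. Mouse Notch2 (ENSMUSG00000027878) stood at 121 ± 0.581 CPM in EV and 148 ± 7.49 CPM in N2NL (SD, n = 3), a log2 fold change of 0.29 ± 0.07 that did not pass (edgeR adjusted p = 0.241). In the authors' deposited comparison Notch2 was higher, past their threshold (DESeq2 adjusted p = 0.0198). No row for the human transgene was found in the raw counts. Whether its reads were counted at mouse Notch2 was not checked, so the level of Notch2 in N2NL is uncertain.

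Of 16682 mouse genes tested, 2 rose and 0 fell in edgeR, with 1242 at an unadjusted p under 0.05; DESeq2 called 25 higher and 5 lower, and limma-voom 1 and 0. The groups did not overlap for 12.7% of genes, where chance gives 10%. The count of 2 became 17 without EV 1, 16 without N2NL 1, 1 without EV 2 and 0 without EV 3, N2NL 2 or N2NL 3. Without the replicate 1 libraries of both groups, which stood apart on the first component, it was 181 higher and 185 lower. The authors' deposited table holds 148 genes past an adjusted p of 0.05 (94 higher, 54 lower), which include both genes and 129 of those 366, all in the same direction.

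Of the 29 mouse lists, 13 were called by camera, 9 higher and 4 lower, of which Klf2 was the only member called over all genes. All 31 neuron genes had fold changes below 0 (median -0.25, camera adjusted p = 1.35e-15, or adjusted p = 0.401 with an estimated correlation), and 6 were lower adjusted over the list alone. The growth cone gene Gap43 stood at 118 ± 7.06 CPM in EV and 88.4 ± 5.28 CPM in N2NL, the stathmin gene Stmn2 at 115 ± 14.6 and 86.7 ± 2.84 CPM, and the tubulin gene Tubb3 at 384 ± 57.2 and 307 ± 16.7 CPM. Stmn4 stood at -0.56 ± 0.15 on the log2 scale, and none of these genes passed over all genes. Of 17 proneural and intermediate progenitor genes, 14 lay below 0 (median -0.16, camera adjusted p = 0.00107, or adjusted p = 0.401 with an estimated correlation) and none passed adjusted over the list alone; Nhlh2 stood at -0.44 ± 0.13.

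Dorsal telencephalon genes were higher as a list (15 of 17 above 0, median 0.11, camera adjusted p = 3.21e-09, or adjusted p = 0.186 with an estimated correlation), with 6 higher adjusted over the list alone. Dmrt3 stood at 43.9 ± 2.62 and 62.7 ± 3.03 CPM, Lhx2, a cortical selector gene, at 74.4 ± 4.88 and 104 ± 10.7 CPM and Six3 at 16.9 ± 1.54 and 23.8 ± 2.25 CPM. Radial glia genes were higher (16 of 21 above 0, median 0.16, camera adjusted p = 1.07e-06, or adjusted p = 0.401 with an estimated correlation), with 6 adjusted over the list alone, among them Ttyh1 (0.46 ± 0.09), Sox3 (0.47 ± 0.11), Ptprz1 (0.38 ± 0.09) and Gli3 (0.26 ± 0.08). Pluripotency genes were higher (20 of 23 above 0, median 0.15, camera adjusted p = 6.52e-08, or adjusted p = 0.186 with an estimated correlation), with 3 adjusted over the list alone; Klf2 rose, and Utf1 and Sall4 stood at 0.39 ± 0.08 and 0.36 ± 0.08. Retina and pigment genes were higher (6 of 8 above 0, median 0.28, camera adjusted p = 1.28e-04, or adjusted p = 0.274 with an estimated correlation), with 3 adjusted over the list alone; Dct stood at 1.89 ± 0.35 and Pmel at 0.78 ± 0.21.

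**Figure D4:**
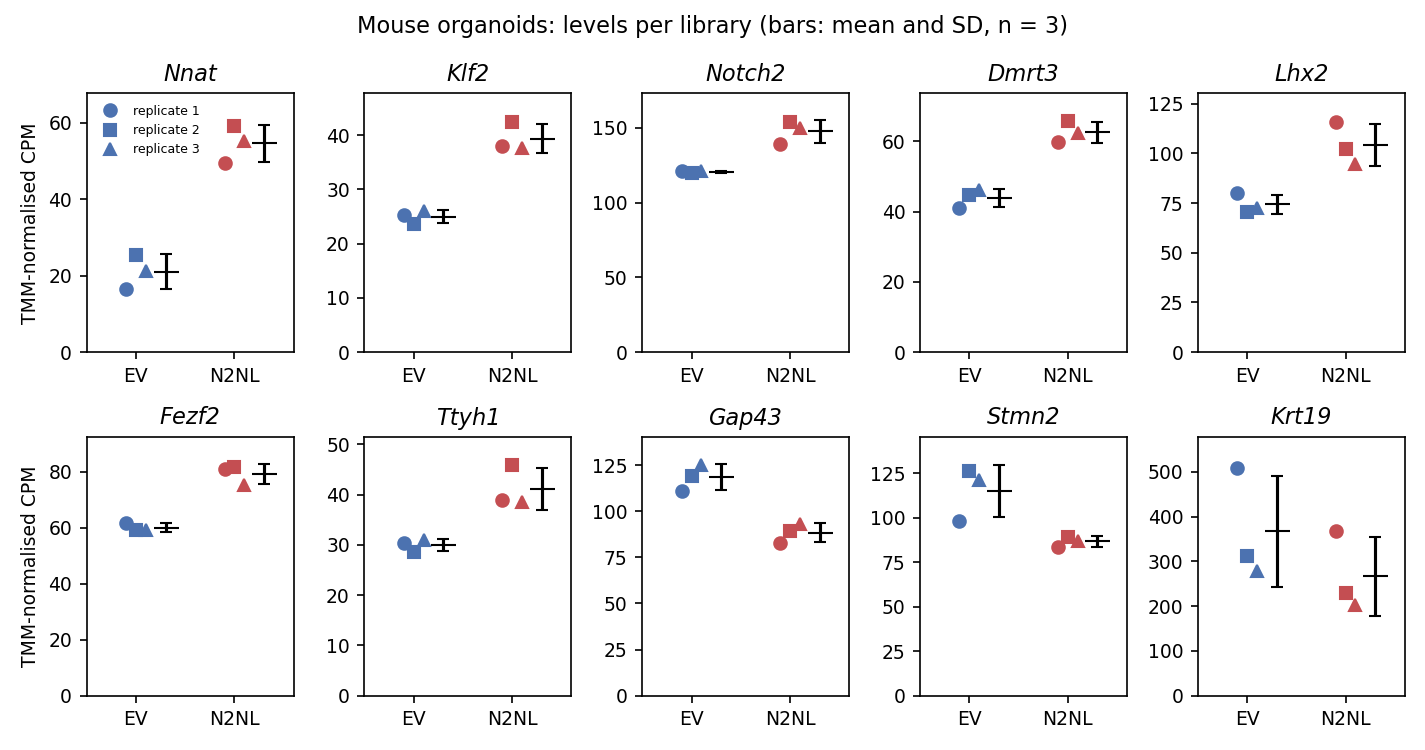
CPM with TMM factors (y axis, starting at 0) of mouse genes named in the text in each EV and N2NL library; points are libraries, and bars give the mean and SD of 3. Nnat stands at 54.5 ± 4.80 CPM in N2NL, with all 3 N2NL libraries above all 3 EV libraries.

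The remaining called lists had medians of at most 0.23 in size. Extracellular matrix genes were higher (17 of 22 above 0, 1 adjusted over the list alone, camera adjusted p = 0.00242, or adjusted p = 0.401 with an estimated correlation). So were Notch ligands, receptors and modifiers (17 of 25 above 0, 2 adjusted over the list alone, camera adjusted p = 0.00515, or adjusted p = 0.474 with an estimated correlation). SHH targets were higher (5 of 7 above 0, none adjusted over the list alone, camera adjusted p = 0.0190, or adjusted p = 0.490 with an estimated correlation), as were WNT targets (10 of 14 above 0, 1 adjusted over the list alone, camera adjusted p = 0.0247, or adjusted p = 0.639 with an estimated correlation). Deep-layer genes were higher (11 of 16 above 0, 1 adjusted over the list alone, camera adjusted p = 0.0256, or adjusted p = 0.401 with an estimated correlation). Examples are Nid2 (0.32 ± 0.08), Dlk1 (0.37 ± 0.10), Ptch1 (0.23 ± 0.08), Sfrp2 (0.34 ± 0.08) and Fezf2 (0.40 ± 0.07). Ribosomal protein genes were lower (66 of 78 below 0, median -0.04, camera adjusted p = 0.0190, or adjusted p = 0.817 with an estimated correlation), as were histone genes (9 of 11 below 0, camera adjusted p = 0.0256, or adjusted p = 0.401 with an estimated correlation). No member of these 2 lists passed adjusted over the list alone. Without N2NL 3 the ribosomal list pointed up and was not called (camera adjusted p = 0.215; 1.19e-26 to 0.855 over the alternatives). Without replicate 3 of both groups, an alternative chosen after seeing the data, it was called higher (camera adjusted p = 0.00184). It was not called without N2NL 2 (0.263) or EV 3 (0.763) either, and 8 lists were called without N2NL 2 and 8 without N2NL 3. Among these 7 lists the extracellular matrix call held in all 6 fits that left out a library; the highest camera adjusted p in such a fit was 0.113 for Notch ligands, receptors and modifiers (without N2NL 2), 0.454 for SHH targets and 0.403 for WNT targets (without EV 1), 0.226 for deep-layer genes (without N2NL 3) and 0.263 for histone genes (without N2NL 2).

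The other 16 lists were not called. Notch targets had a median of 0.07 over 11 genes, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.129); Sox9, a progenitor transcription factor, stood at 60.4 ± 5.61 and 80.5 ± 4.58 CPM. Neural crest genes had 1 lower adjusted over the list alone (0.971, median 0.01, mean -0.05), and Sox10 stood at -0.60 ± 0.16. None passed adjusted over the list alone among ventral telencephalon (camera adjusted p = 0.582, median -0.03, mean 0.08), hem and choroid (0.507), midbrain and hindbrain (0.385), surface epithelium (0.582), mesoderm and endoderm (0.582), endothelium and blood (0.120), mitotic (0.240), astroglia (0.713, median 0.01, mean -0.02), hypoxia (0.845, median -0.01, mean 0.01), stress (0.703), p53 (0.689), immediate early (0.973, median 0.04, mean -0.03), cholesterol (0.385) and mitochondrially encoded genes (0.388). Krt19, a surface epithelium keratin, stood at 367 ± 124 and 267 ± 88.4 CPM, and its list was lower without the replicate 1 libraries of both groups (camera adjusted p = 0.00115). In that fit the endothelium, blood and microglia list was lower as well (camera adjusted p = 1.51e-04), and the SHH (0.143), WNT (0.0647), deep-layer (0.0548) and histone (0.0516) lists were not called. Of these 16 lists, endothelium and blood genes were called lower without EV 1 or N2NL 1 (lowest camera adjusted p = 0.00299) and surface epithelium genes without N2NL 1 (0.00144). Hem and choroid (0.00609) and midbrain and hindbrain genes (0.0129) were called lower without EV 1. Without EV 3, Notch targets were called higher (0.0181) and mitochondrially encoded genes lower (0.00168).

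Loss and gain of NOTCH2NL are opposite manipulations, so the last comparison asks whether fold changes were opposite in the 2 species. Across 399 matched list genes the Spearman correlation was 0.105 and Pearson's 0.0927, and 57.6% had the same sign. Genes are not independent, so no p is attached. SIX3 rose in human KO (2.03 ± 0.19), and mouse Six3 stood at 0.50 ± 0.11. TTYH1 fell in KO (-0.48 ± 0.08), and Ttyh1 stood at 0.46 ± 0.09. TUBB3 fell in KO (-0.52 ± 0.12), and Tubb3 stood at -0.33 ± 0.10. No matched gene was called in both species in edgeR (37 called in human, 0 in mouse), so no Fisher exact test was possible; DESeq2 in both species called 2. As sets in mouse, the 16 matched genes higher in KO and the 21 lower in KO were not called (camera adjusted p = 0.405 for both, 0.495 with an estimated correlation). The reverse was not run, since edgeR called only 2 mouse genes.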

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

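The single result here comes from data outside the comparisons of the report, and its reading was chosen after the values were seen. The authors' deposited mouse table has a row for the human NOTCH2NL transgene, which was not used in the comparisons here. Its values are 0 in all 3 EV libraries and 801, 709 and 740 in N2NL 1 to 3, on the authors' normalized scale. It was taken up because this signal stands above the control libraries; it goes with the mouse labels and was not tested.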

How the results depend on the processing

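The fits that left out a replicate number from both groups and DESeq2 with the block were chosen after seeing the data; the other alternatives were planned. Of 62 named human genes past the threshold, 17 stayed past it under every alternative. Of 1177 values over the alternatives 910 kept their call, 267 lost it and none changed direction. For the 6 human lists 98 of 114 values kept the call, for the 2 mouse genes 26 of 38 and for the 13 mouse lists 188 of 247. Of results not past the threshold, 76 of 662 values became calls for 35 human genes, 42 of 473 for 25 human lists (13 lists stayed uncalled under all), 80 of 1482 for 80 mouse genes and 14 of 304 for 16 mouse lists (10 stayed uncalled). The mouse ribosomal protein list changed direction in 2 fits, to an adjusted p of 0.215 without N2NL replicate 3 and 0.00184 without replicate 3 of both groups, and ran from 8.10e-15 to 0.763 over the fits that left out 1 library. The cause was not tested.

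In human, 593 genes were higher in DESeq2, and 957 were higher and 1198 lower with no filter, which tests more genes. Leaving out 1 library gave 94 to 661 higher and 127 to 779 lower. Leaving out replicate 1, 2 or 3 of both groups gave 221, 130 and 31 higher and 276, 144 and 36 lower, with fewer libraries in each fit. Lists called numbered 0 with an estimated correlation, 1 with fry, 13 with no filter, 6 to 12 without 1 library, and 11 and 10 without replicate 1 or 3 of both groups. In mouse, DESeq2 gave 25 higher and 5 lower, no filter 79 and 38, limma-voom and the fit without the robust step 1 higher each. Leaving out 1 library gave 0 to 6 higher and 0 to 11 lower, and 8 to 15 lists. Without replicate 1, 2 or 3 of both groups 181, 1 and 0 genes were higher, and without replicate 1 of both 185 were lower. No mouse list was called with an estimated correlation (0) or fry (0). Between species, DESeq2 called 2 genes in both and the mouse fit without replicate 1 of both groups 5, against 0, and 0 without any single library. The correlation stayed between 0.062 and 0.1713 without 1 library. The causes were not tested.

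Libraries with the same number did not deviate together throughout: correlations of deviations were 0.216, -0.113 and 0.126 in human and 0.143, 0.016 and -0.005 in mouse, and not every library correlated best with its own number. With the replicate number as a block, edgeR called 431 higher and 468 lower in human (730 genes shared) and 8 higher and 13 lower in mouse, and DESeq2 with the block 11 and 15 in mouse. Of lists not called without it, the block called dorsal telencephalon (camera adjusted p = 0.0194) and retina and pigment epithelium (0.0112) in human, and surface epithelium (0.00293) and endothelium, blood and microglia (0.0183) in mouse; it ended no list call. Mouse chromosome shifts were not run. At these depths a floor of 3 counts stands for at most 0.195 CPM. NOTCH2NL, at 3 to 5 counts in WT, did not pass the filter on low counts.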

Other observations

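The tests of explanations and the splits in this part were chosen after the results they bear on had been seen; the fits that left out 1 library, the other scalings and the estimated correlation were planned, and leaving out a replicate number from both groups was not. The genes named here outside the rule for naming were chosen after their values were seen. Besides the 5 genes named in the report, 3 more with at least 30 counts over WT had 0 counts in all KO libraries: ZFP28 (618 counts over WT, at least 209-fold lower), ZNF596 (225, at least 75.7-fold) and ZNF726 (131, at least 44.4-fold). By symbol, 5 of these 8 genes are zinc finger genes, 3 of them on chromosome 19. That class was noticed from the same 8 names, so it was not tested. In the other direction KLF8, a Kruppel-like factor on chromosome X, had 0 counts in WT and 49, 59 and 53 in KO 1 to 3, at least 53.1-fold higher.

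A few keratin, S100 and SPRR genes, picked for their counts in KO 3, stood apart there: S100A9 had 107 counts, KRT6A 81, KRT5 70, SPRR1B 52 and S100A8 46. The other 5 libraries held 0 counts of S100A9, S100A8 and SPRR1B, 1 count of KRT6A (KO 2) and 4 counts of KRT5 (WT 2). None of these genes was tested. Of other epithelial genes looked at, KRT19 had 28 counts in KO 3 and 7 to 12 in the rest, and KRT14, the partner keratin of KRT5, 1 and 0. The cadherin gene CDH1 had 8 in KO 3 and 3 to 14 in the rest, the adhesion gene EPCAM 116 and 93 to 131, and KRT8 212 and 73 to 291.

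In the authors' deposited mouse table, 7 of 33 neuron genes were lower with NOTCH2NL, among them Gap43, Stmn2 and Tubb3. There 6 of 17 dorsal telencephalon genes were higher, among them Lhx2 and Emx2, and 4 of 21 radial glia genes, Id4, Ttyh1, Sox3 and Ptprz1. Of the Notch lists, 1 of 11 targets (Sox9) and 1 of 26 ligands, receptors and modifiers (Notch2) were higher there, and none was lower. Whether transgene reads were counted at Notch2 was not checked there either. As sets in the human libraries, the 83 matched genes higher in that table had a median log2 fold change of -0.05 in KO (camera adjusted p = 0.414) and the 33 lower ones -0.24 (camera adjusted p = 0.0802, or adjusted p = 0.641 with an estimated correlation, fry adjusted p = 0.263). The lower set was picked for going down with NOTCH2NL in mouse, and its median in human KO, the opposite manipulation, lay below 0 as well.

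The 8 human genes at 0 in KO lie on 5 chromosomes. A single deleted stretch is argued against by the 5 chromosomes, while a separate loss at each locus stays open. PUS7L and IRAK4 are neighbours, both at 0; of other neighbours, TWF1 beside IRAK4 stood at -0.03 and ZKSCAN1 beside TRIM4 at -0.01, and ZSCAN18 beside ZNF135 fell (-0.37, edgeR adjusted p = 0.0420). The KO group carries 1 line code, so a silencing or loss that arose in that line may explain the 0 counts as well as the genotype, and line and genotype cannot be told apart here.

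The ventral telencephalon list was higher in KO by camera (adjusted p = 6.00e-11, or adjusted p = 0.680 with an estimated correlation), with 5 of 11 members called and 3 below 0, GAD1 (-0.13), GSX1 (-0.33) and SHH (-1.65). A single library as the whole source is argued against by a lowest list median of 0.83 over the 6 fits that left out a library (SD 0.26 over these fits). At least 5 members were called under each of 3 scalings. The scalings differed little (median log2 fold change over all tested genes -0.0047, -0.0019 and 0.024), so that check could hardly have come out otherwise. An equal rise of markers of all other types and regions is argued against by 7 lower and 8 higher of 139 tested. The lower ones were SOX8, PAX8, LUM, GPM6A, PMEL, MAPT and TUBB3. The main cell type was not defined, and GPM6A, MAPT and TUBB3 are neuron genes, so a lower share of it stays open. A difference in regional fate that follows the genotype stays open too. The KO group has 1 line code, so a trait of the line in place of the genotype cannot be told apart from such a difference.

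The mouse calls depend on the replicate 1 libraries, since 366 genes were called without them and 2 with them. Fewer libraries alone are argued against, because leaving out replicate 2 or 3 of both groups gave at most 1 call. A shared deviation of the replicate 1 libraries, such as a common batch, could add spread within both groups; the correlation of their deviations was 0.143, the highest of the 9 pairs of an EV and an N2NL library (next 0.111). The highest of 9 pairs falls on a given pair by chance in 1 of 9 cases and no label names a batch. EV 1 and N2NL 1 lay together on the first component (-21.98 and -19.08) and on opposite sides of the second (21.53 and -19.97). The replicate number as a block, which takes up a deviation equal in both groups, gave 8 higher and 13 lower in edgeR. These calls were far fewer than the 366 without replicate 1, and a shared deviation stays open. The transgene as a source of the difference was not tested separately. With 1 line code in each mouse group, it cannot be told apart from a trait of the line.

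Other splits of the 6 libraries of a species into 3 and 3 number 10 with the real one, too few for a share under 0.05. In human the real split called 932 genes, and the highest other called 21, so 1 of 10 splits reached the real count. For human lists the real split gave 6 and the highest other 13 (8 of 10 splits gave at least 6), and for chromosomes 1 and 2 (4 of 10). In mouse the real split called 2 genes and the split that set EV 1, EV 2 and N2NL 1 against the rest called 8 (2 of 10 splits gave at least 2). The 3 other splits with EV 1 and N2NL 1 on one side called 0 genes each. For mouse lists the real split gave 13 and the highest other 12 (1 of 10). Over 100 pairs of splits, 49 gave a correlation between species at least as far from 0 as the real 0.105, and the highest other was 0.283, so chance is not excluded for it.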
